A study of Danio rerio with 12 samples.

How the data were processed

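Whole wild-type zebrafish larvae at 4 days post fertilisation gave 12 poly(A) RNA-seq libraries in 4 groups of 3. The groups were untreated control (replicates 2, 3 and 4), 20 mg/L PFOS (PFOS20, replicates 2, 3 and 4), 20 mg/L OBS (OBS20, replicates 1, 2 and 3) and 30 mg/L OBS (OBS30, replicates 1, 3 and 4). The deposited values are TPM, a length-scaled share of transcripts that the authors scaled so that each library adds up to the same total over 44667 genes and loci. The submitters' notes name HISAT2, StringTie, RSEM and the GRCz11 assembly without versions or roles. Group means in the same table equalled the means of the libraries to within 3.3e-05 TPM and were not used in tests. The table holds 32520 Ensembl genes and 12147 loci assembled from the reads. Identifiers and symbols were taken from the table, 29201 of the Ensembl identifiers were also in a reference table of names, and no genomic positions were assigned because the table gives none and the reference positions were of another assembly. No counts were used, so the depth per library is unknown, no counting interval could be given, and the precision comes from the spread between libraries.

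Genes and loci with at least 1 TPM in at least 3 of the 12 libraries were tested (30674). Each group has 3 libraries, so a gene near 0 in control could pass through an exposed group alone. List counts are of the members that passed, and this can raise the share called higher. Values were log2(TPM + 1), and 1 model in limma 3.58.1 (R 4.3.3) with eBayes and a mean-variance trend held all 12 libraries with a term for the group. It gave 5 contrasts: each exposure against control, OBS20 against PFOS20, and OBS30 against OBS20. A moderated F test covered the 3 exposures against control. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its contrast. All tests were two-sided. The groups, contrasts, gene lists, naming rule and first set of alternatives were fixed before the data were examined.

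The 40 gene lists, of cell types, pathways and organs, held 1336 tested genes, of which 45 were in more than 1 list. The hepatocyte list shares members with the complement and lipoprotein lists, so calls of these lists are not separate support. Each list was tested in limma by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, with adjustment over the lists of a contrast. The correlation was estimated from the residuals of all 12 libraries, OBS20 replicate 3 included, and not again without that library. A list or map not called with it is not shown to be unchanged. Where several entries of the table shared a symbol, the one with the highest mean TPM stood for the gene. Called members were also counted after adjustment over the list alone. The mean of each list per library, a measure added after the data were seen, gave the difference between OBS20 and PFOS20 with a 95% interval from the spread pooled over the 4 groups (8 degrees of freedom). Such an interval is too narrow where the groups compared spread more than the others. None was taken from the 6 libraries compared alone.

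Genes were named by a rule. It took the 7 highest and 7 lowest log2 changes in each contrast with control, and 5 and 5 in the others. These came from called genes whose libraries did not overlap, with a mean of at least 5 TPM in the higher group and an assigned symbol. It added up to 2 called members per direction of each list that passed camera or had at least 3 called members, or only of lists that passed camera where this would name more than 30 genes in a contrast. It also added a panel of 18 genes, of which 17 were tested. Genes under the list part of the rule that are not printed are given by count only. Several symbols in the table had become dates and were not used as names.

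Alternatives were another pseudocount (0.1), no filter, a mean of at least 5 TPM, quantile normalisation, median-of-ratios scaling, a replicate block, a fit of only the 6 libraries compared and the removal of each library in turn. Removal of a trend over gene length, list tests without OBS20 replicate 3 and tests of KEGG maps were added after the data were seen. Other splits of the 6 libraries of a contrast, and 100 regroupings of all 12, were fitted in the same way. The similarity of responses was set against 100 simulated draws without a change. In these all libraries, controls included, were drawn around the control means with residuals shuffled over the 12 libraries and given a random sign. The pipeline was tested on simulated data, drawn around the control means with the spread of each gene, in which 1 group had genes changed by a known fold. Of genes changed 1.5-fold it called 11.9% to 25.4% by contrast, and of genes changed 2-fold 47.8% to 64.2%. Of genes changed 4-fold it called 83.3% to 93.9%, and it called 3 to 10 unchanged genes. The changed genes were drawn only from those with a mean log2(TPM + 1) at or above that of 5 TPM. The noise was independent between genes, with the same spread in all groups. These rates therefore do not cover changed genes of lower TPM, or a library as far apart as OBS20 replicate 3. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the table and drew the figures.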

Results

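RNA from whole zebrafish larvae at 4 days post fertilisation was sequenced after exposure to PFOS, to OBS or to neither. PFOS is a legacy surfactant with a perfluoroalkyl chain on a sulfonate group. OBS, sodium p-perfluorous nonenoxybenzene sulfonate, carries a perfluoroalkenyl chain joined through oxygen to a benzenesulfonate, and the series names it as an emerging alternative to PFOS. The 12 libraries formed 4 groups of 3: untreated control, 20 mg/L PFOS (PFOS20), 20 mg/L OBS (OBS20) and 30 mg/L OBS (OBS30). The series asks about histological alterations, oxidative stress and immune aberrations in larvae. The values were TPM, a length-scaled share of transcripts, for 44667 genes and assembled loci, of which 30674 were tested, and the read depth behind them is unknown. The labels do not say whether replicates were separate clutches or pools, so each p-value measures only the spread between these samples.

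Within each group, the median TPM over all genes and loci was 2.09 ± 0.035 in control, 1.80 ± 0.235 in PFOS20, 1.89 ± 0.541 in OBS20 and 2.17 ± 0.238 in OBS30 (SD, n = 3 each). OBS20 replicate 3 stood apart, with a median TPM of 1.27 and 23942 genes or loci at 1 TPM or more, against 28115 in OBS20 replicate 2. Ribosomal protein transcripts took 19.1% of its TPM, and its 100 most abundant transcripts took 42.8%. PFOS20 replicate 2 had a median TPM of 1.57. Transcripts of the mitochondrial genome took 7.78% ± 0.478 of TPM in control, 10.18% ± 0.324 in PFOS20, 7.94% ± 0.493 in OBS20 and 8.62% ± 0.245 in OBS30 (SD, n = 3). Changes below are differences in mean log2(TPM + 1) with the standard error of the fit, a relative median is the median of a list minus that of all genes tested, and other list medians are unadjusted.

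The first comparison asked how larvae in 20 mg/L PFOS, the legacy compound, differed from untreated larvae. Part of the genes in the cytokine, matrix remodelling, heat shock and integrated stress response lists rose in PFOS20 (17 of 31, 24 of 47, 12 of 33 and 8 of 33), and camera called these lists higher but not with an estimated correlation. The interleukin gene il1b (ENSDARG00000098700), a fever and inflammation signal, went from 1.01 ± 0.488 TPM in control to 34.3 ± 3.41 in PFOS20 (SD, n = 3), a log2 change of 4.16 ± 0.39 with adjusted p = 1.2e-04. The leptin gene lepb (ENSDARG00000045548), which is induced in regenerating fish tissue, rose by 4.47 ± 0.32 from 0.937 ± 0.442 to 41.3 ± 0.937 TPM. The parathyroid hormone gene pth1a, which regulates calcium, rose by 4.32 ± 0.17. The matrix metalloproteinase genes mmp9 and mmp13a, whose products cleave extracellular matrix, rose by 3.47 ± 0.19 and 3.46 ± 0.22. The neutrophil chemokine gene cxcl8a rose by 1.86 ± 0.29, and mpx, which encodes the neutrophil myeloperoxidase, by 0.94 ± 0.18.

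Among the 31 genes of cytokines and inflammatory signalling that passed the filter, 17 rose, 1 fell and 13 were not called in PFOS20, and 18 rose and 2 fell when adjusted over the list alone. Their relative median was 0.98 (camera, adjusted p = 1.4e-12), with adjusted p = 0.088 with an estimated correlation. The prostaglandin synthase gene ptgs2a rose by 1.60 ± 0.15. Of 47 genes of extracellular matrix remodelling and wound response, 24 rose and 2 fell, and 24 and 4 adjusted over the list alone, with adjusted p = 2.7e-15 and adjusted p = 0.16 with an estimated correlation. In this list the transcription factor gene fosl1a, an AP-1 subunit, rose by 3.26 ± 0.31. Of 15 neutrophil markers 8 rose and 2 fell, counts that were equal when adjusted over the list alone (adjusted p = 2.1e-06, and adjusted p = 0.11 with an estimated correlation). Of 21 macrophage and microglia markers 5 rose and 1 fell, and 7 and 1 adjusted over the list alone (adjusted p = 1.3e-05, and adjusted p = 0.16 with an estimated correlation). Among these, the lipid carrier gene apoeb, a microglial marker, rose by 1.39 ± 0.10.

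Some genes of the heat shock, integrated stress response, glycolysis and mitochondrial lists rose in PFOS20 as well, and none of these list calls held with an estimated correlation. Among 33 heat shock protein genes 12 rose and 3 fell, and 13 and 3 adjusted over the list alone, with adjusted p = 9.3e-07 and adjusted p = 0.16 with an estimated correlation. The small heat shock gene hspb9 rose by 2.97 ± 0.18 and hsp70l by 2.27 ± 0.13, whereas hspa4b fell by 2.71 ± 0.42. In the integrated stress response and amino acid synthesis list, 8 of 33 genes rose and 1 fell, with equal counts adjusted over the list alone (adjusted p = 7.4e-06, and adjusted p = 0.16 with an estimated correlation). The stress transcription factor genes cebpb and atf3 rose by 2.58 ± 0.22 and 2.33 ± 0.18. Of 47 genes of glycolysis and hypoxia response 16 rose and 5 fell, the latter count reaching 9 without PFOS20 replicate 4. Adjusted over the list alone 18 rose and 7 fell (adjusted p = 1.7e-06, and adjusted p = 0.29 with an estimated correlation). The aldolase gene aldoaa rose from 433 ± 12.4 to 1442 ± 17.6 TPM (SD, n = 3). Of 13 mitochondrially encoded genes 7 rose and 0 fell, and 8 and 0 adjusted over the list alone (adjusted p = 4.0e-07, and adjusted p = 0.15 with an estimated correlation). Among these mt-cyb, a cytochrome b gene, rose by 0.65 ± 0.06.

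Antioxidant and Nrf2 target genes moved both ways in PFOS20. Of 49, 16 rose and 7 fell, equal to the counts adjusted over the list alone. The count of those that fell was 4 without control replicate 3, PFOS20 replicate 2 or PFOS20 replicate 3. The list passed as higher (adjusted p = 2.7e-05), with adjusted p = 0.16 with an estimated correlation. The ferritin gene fthl27, for iron storage, rose by 1.67 ± 0.09, the peroxiredoxin gene prdx1 by 1.24 ± 0.11 and the haem oxygenase gene hmox1a by 1.31 ± 0.28. The detoxification genes nqo1 and gclc were not called, at 0.06 ± 0.10 and 0.22 ± 0.12. The aryl hydrocarbon receptor target cyp1a, a monooxygenase gene, rose by 0.79 ± 0.15, and cyp1c2 by 1.78 ± 0.18. Of 12 such targets 5 rose and 0 fell, and 6 and 0 adjusted over the list alone (adjusted p = 3.2e-04, and adjusted p = 0.29 with an estimated correlation).

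Part of the neural, proliferation, pancreas and cholesterol synthesis genes were lower in PFOS20, in lists that camera called, but not with an estimated correlation. Of 57 neuron and glia markers 35 fell, 0 rose and 22 were not called, and 40 fell and 1 rose adjusted over the list alone. Their relative median was -0.90 (adjusted p = 1.1e-11), with adjusted p = 0.29 with an estimated correlation. The tubulin gene tuba1c, expressed in developing neurons, fell from 534 ± 17.3 to 183 ± 50.4 TPM, a log2 change of -1.57 ± 0.14, and tubb5 fell by 1.24 ± 0.11. The list's median against control was -1.31, -1.15 and -0.62 in PFOS20 replicates 2, 3 and 4, where the median of all genes was -0.25, -0.12 and -0.03. Of 50 genes of proliferation and DNA replication 37 fell and 0 rose, and 46 and 0 adjusted over the list alone (adjusted p = 2.7e-17, and adjusted p = 0.16 with an estimated correlation). The chromatin gene hmgb2b fell by 0.87 ± 0.07 and the microtubule regulator stmn1a by 1.13 ± 0.11. Of 21 exocrine pancreas markers 13 fell and 0 rose, and 17 and 0 adjusted over the list alone (adjusted p = 1.7e-08, and adjusted p = 0.19 with an estimated correlation). The trypsin gene prss59.1 fell by 1.60 ± 0.21. Of 31 genes of cholesterol synthesis 18 fell and 1 rose, the former count being 11 without control replicate 3 and 10 without PFOS20 replicate 2. Adjusted over the list alone 20 fell and 1 rose (adjusted p = 7.1e-05, and adjusted p = 0.46 with an estimated correlation). The sterol demethylase gene cyp51 fell by 1.18 ± 0.16.

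The lens, photoreceptor and complement lists were also called lower in PFOS20, but not with an estimated correlation. Of 51 lens genes 25 fell and 0 rose, and 32 and 0 adjusted over the list alone (adjusted p = 1.4e-07, and adjusted p = 0.16 with an estimated correlation). The lens count was 15 without control replicate 4, and 1 rose without control replicate 3. Of 57 photoreceptor genes 16 fell and 1 rose, and 20 and 1 adjusted over the list alone (adjusted p = 1.3e-04, and adjusted p = 0.35 with an estimated correlation). The count of 16 was 8 without control replicate 3, 9 and 10 without PFOS20 replicates 2 and 3, and 25 without OBS20 replicate 3. Of 43 genes of complement, coagulation and acute phase 15 fell and 3 rose, and 18 and 4 adjusted over the list alone (adjusted p = 0.018, and adjusted p = 0.53 with an estimated correlation), with 1 rising without PFOS20 replicate 3. Hepatocyte markers had 13 lower and 5 higher of 35, equal to the counts adjusted over the list alone, and the list was not called (adjusted p = 0.11).

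In all, 5610 of the 30674 genes and loci were called in PFOS20 by limma, 1947 higher and 3663 lower. Of these 684 and 1244 changed by at least 2-fold, against 987 and 928 after quantile normalisation. Camera called 19 of the 40 lists higher and 7 lower, 0 of them with an estimated correlation. Over all genes and loci tested, 43.3% had all 3 libraries of one group above all 3 of the other, against the 10% that chance gives on average over splits. Genes shift together within a library, so the share of a single split can lie away from 10% by chance. The shares of other splits were not computed, here or for the contrasts below. The largest falls included ahsg2, a liver-secreted fetuin gene, at -3.68 ± 0.19, cfd, a complement protease gene, at -3.20 ± 0.43, and the lectin gene itln3 at -2.34 ± 0.21. The median of all genes was -0.13 as scaled by the authors and 0.00 after median-of-ratios scaling, and the share called higher went from 34.7% to 50.1%, or to 48.3% after quantile normalisation. The count was 3646, 3449 and 3330 without control replicates 2, 3 and 4, 3482 and 3090 without PFOS20 replicates 2 and 3, and 8716 without OBS20 replicate 3, whose spread enters the pooled residual.

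**Figure D1:**
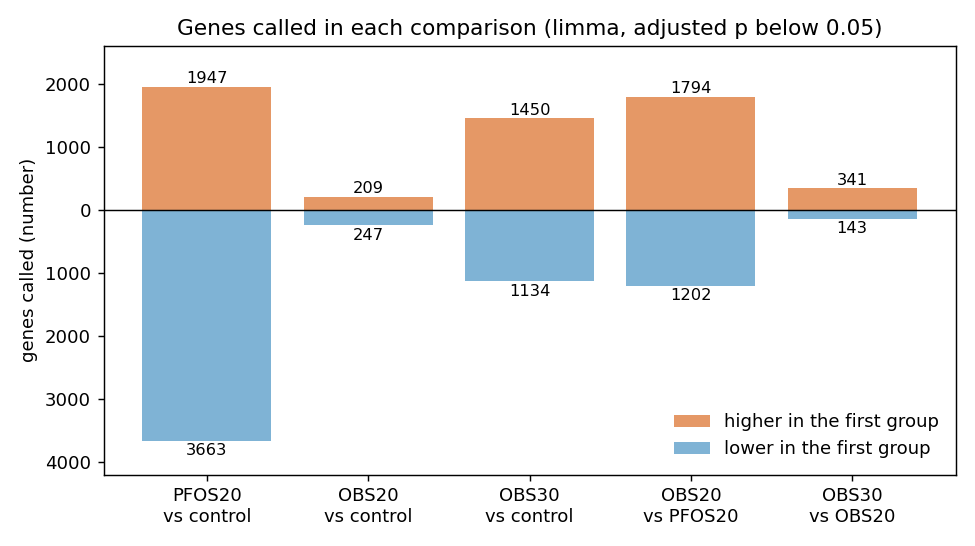
Number of genes called in each comparison by limma at an adjusted p below 0.05, with bars above 0 for genes higher and bars below 0 for genes lower in the group named first. PFOS20 against control has 1947 higher and 3663 lower, and OBS20 against control 209 and 247.

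The second comparison asked the same of OBS, the alternative compound, at 20 mg/L. Part of the antioxidant and aryl hydrocarbon receptor target genes were higher in OBS20 than in control (12 of 49 and 6 of 12), and part of the hepatocyte, enterocyte and cholesterol synthesis genes lower (12 of 35, 7 of 43 and 10 of 31). Of these list calls the antioxidant one held with an estimated correlation, and the others did not. The glutathione transferase gene gstp1 (ENSDARG00000104068), which conjugates electrophiles, went from 504 ± 28.1 to 1961 ± 146 TPM (SD, n = 3), a log2 change of 1.96 ± 0.07 with adjusted p = 3.4e-07. The peroxiredoxin gene prdx1 rose by 2.00 ± 0.11, the cytochrome P450 gene cyp2k18 by 3.40 ± 0.27 and the vitamin B12 carrier gene tcnbb by 2.27 ± 0.14. The hepatocyte gene fetub fell by 1.59 ± 0.11 from 186 ± 27.2 to 61.0 ± 4.99 TPM, and the intestinal retinol-binding gene rbp2a by 1.46 ± 0.16.

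Of 49 antioxidant and Nrf2 target genes 12 rose, 0 fell and 37 were not called in OBS20, and 21 rose and 1 fell adjusted over the list alone. Their relative median was 0.37 (adjusted p = 4.7e-18), and this call held with adjusted p = 0.02 with an estimated correlation. Among 12 aryl hydrocarbon receptor targets 6 rose and 0 fell, and 7 and 0 adjusted over the list alone (adjusted p = 8.5e-12, and adjusted p = 0.11 with an estimated correlation). The list of other xenobiotic metabolism genes was not called, with 9 higher and 5 lower of 58, and 14 and 11 adjusted over the list alone (adjusted p = 0.098), the 5 being 3 without control replicate 2. The monooxygenase gene cyp1a rose from 44.3 ± 8.77 to 118 ± 16.6 TPM (SD, n = 3). Of 60 skeletal muscle markers 7 rose and 0 fell, with 12 rising and 1 falling adjusted over the list alone (adjusted p = 5.2e-13, and adjusted p = 0.015 with an estimated correlation). That count of 7 was 2 without control replicate 2 or 4, 3 without control replicate 3, OBS20 replicate 1, OBS20 replicate 2 or OBS30 replicate 3, and 4 without PFOS20 replicate 3, OBS30 replicate 1 or OBS30 replicate 4. The muscle list's median against control was 0.16, 0.11 and 0.19 in OBS20 replicates 1, 2 and 3. All genes had medians of 0.04, 0.09 and -0.35 there, so the list's lead over other genes was widest in OBS20 replicate 3. The test with an estimated correlation was not run without that library, for this list or the antioxidant one.

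Hepatocyte markers fell in OBS20 in 12 of 35 genes and rose in 1, and in 24 and 4 adjusted over the list alone (adjusted p = 1.7e-14, and adjusted p = 0.088 with an estimated correlation). Of 43 genes of complement, coagulation and acute phase 13 fell and 0 rose, and 30 and 1 adjusted over the list alone (adjusted p = 4.5e-22, and adjusted p = 0.078 with an estimated correlation). The count of 13 was 6 without control replicate 2, 7 without control replicate 3 and 8 without OBS20 replicate 1. The antiprotease gene serpina1l, which is in the hepatocyte list as well, fell by 1.19 ± 0.11 and the fetuin gene ahsg2 by 3.48 ± 0.19. Of 31 cholesterol synthesis genes 10 fell and 0 rose, and 15 and 0 adjusted over the list alone (adjusted p = 2.8e-14, and adjusted p = 0.18 with an estimated correlation). The count of 10 was 5 without control replicate 2 or 3 and 6 without control replicate 4. The sterol synthesis genes msmo1 and cyp51 fell by 1.56 ± 0.18 and 1.39 ± 0.16. Of 43 enterocyte markers 7 fell and 0 rose, and 18 fell and 1 rose adjusted over the list alone (adjusted p = 3.3e-11, and adjusted p = 0.18 with an estimated correlation), with 4 falling without OBS20 replicate 1. Of 31 genes of cytokines and inflammatory signalling 0 rose and 0 fell in limma, and 0 rose and 2 fell adjusted over the list alone (adjusted p = 0.8 by camera), with 1 falling in limma without OBS20 replicate 2. The interleukin gene il1b stood at 1.37 ± 0.175 TPM in OBS20 (SD, n = 3), a log2 change of 0.26 ± 0.39 with adjusted p = 0.87. Neuron and glia markers had 1 higher and 0 lower of 57, and 1 and 0 adjusted over the list alone (adjusted p = 0.59), with 0 higher without any control library or OBS20 replicate 1. Their median was -0.36 in OBS20 replicate 3, where the median of all genes was -0.35, and -0.03 and 0.03 in the other replicates.

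In all, 456 genes and loci were called in OBS20, 209 higher and 247 lower. Over all genes and loci tested, 15.0% had no overlap between the libraries of the groups, against the 10% that chance gives on average over splits, and this gap was not tested. Of those called 96 and 152 changed by at least 2-fold, against 130 and 116 after quantile normalisation. Camera called 11 lists higher and 9 lower, of which 2 held with an estimated correlation. The share called higher was 45.8%, against 57.7% after quantile normalisation, 53.2% after median-of-ratios scaling, 55.2% among genes with a mean TPM of at least 5 and 59.8% without OBS20 replicate 3. Without control replicates 2, 3 and 4 the count was 247, 246 and 275, and without OBS20 replicate 1 it was 230. A fit of the 6 libraries alone called 109. Without OBS20 replicate 3, 15 of those lists were called again, and the neutrophil list, with 0 members higher and 0 lower, was among those that were not (adjusted p = 0.59 without it).

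**Figure D2:**
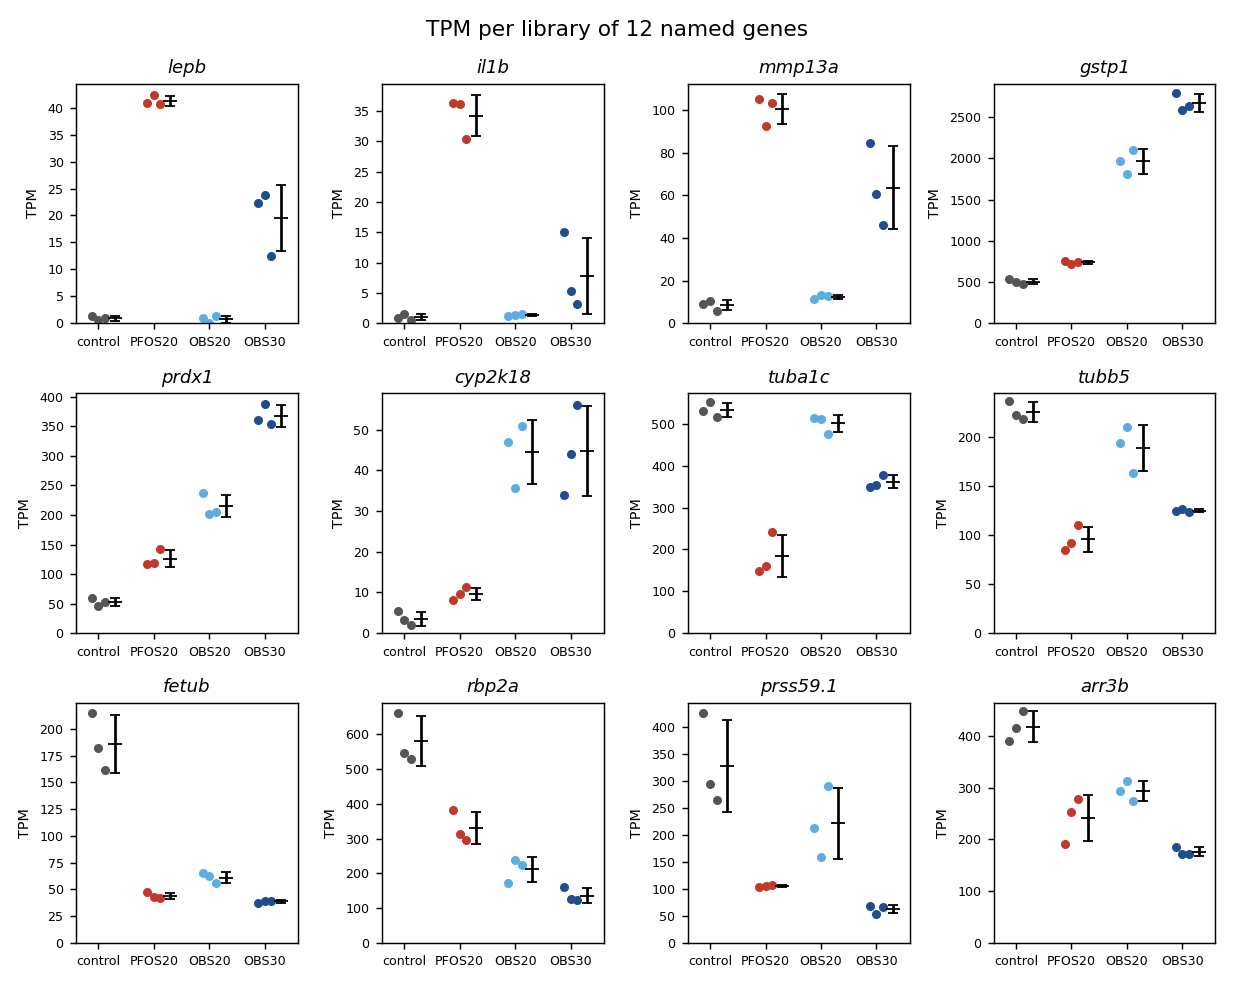
TPM of 12 named genes in each of the 12 libraries (coloured points), with the mean and SD of each group of 3 in black. The il1b points of PFOS20 average 34.3 TPM against 1.01 in control and 1.37 in OBS20, and the gstp1 points of OBS20 and OBS30 average 1961 and 2668 TPM against 504 in control.

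The third comparison concerned 30 mg/L OBS, a dose without a matching PFOS group. Part of the antioxidant, cytokine, wound and glycolysis genes were higher in OBS30 than in control (19 of 49, 12 of 31, 21 of 47 and 23 of 47). Part of the enterocyte, hepatocyte, pancreas, lens and photoreceptor genes were lower (25 of 43, 21 of 35, 8 of 21, 23 of 51 and 17 of 57), and none of these list calls held with an estimated correlation. Against control, prdx1 rose by 2.78 ± 0.11 to 368 ± 18.5 TPM and gstp1 reached 2668 ± 108 TPM, against 504 ± 28.1 in control (SD, n = 3). The heat shock gene hsp70l rose by 2.67 ± 0.13, lepb by 3.38 ± 0.32, mmp13a by 2.77 ± 0.22 and mmp9 by 2.31 ± 0.19. The intestinal gene rbp2a fell by 2.09 ± 0.16, the liver gene fetub by 2.23 ± 0.11, the trypsin gene prss59.1 by 2.34 ± 0.21 and the amylase gene amy2a by 2.47 ± 0.21.

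Of 49 antioxidant and Nrf2 target genes 19 rose and 2 fell in OBS30, and 27 and 5 adjusted over the list alone (adjusted p = 3.4e-11, and adjusted p = 0.071 with an estimated correlation). The haem oxygenase gene hmox1a rose by 1.60 ± 0.28, while prdx2 fell by 0.63 ± 0.08. Of 31 genes of cytokines and inflammatory signalling 12 rose and 0 fell, and 15 and 1 adjusted over the list alone (adjusted p = 2.2e-08, and adjusted p = 0.071 with an estimated correlation), with 7 rising without control replicate 4. The prostaglandin synthase gene ptgs2a rose by 1.28 ± 0.15 and the cytokine signalling inhibitor gene socs3b by 1.33 ± 0.17. The il1b level was 7.86 ± 6.29 TPM, a log2 change of 1.93 ± 0.39 with adjusted p = 0.011, a call that a fit of the 6 libraries alone did not make. Of 47 genes of extracellular matrix remodelling and wound response 21 rose and 0 fell, and 26 and 0 adjusted over the list alone (adjusted p = 1.6e-11, and adjusted p = 0.13 with an estimated correlation). Of 47 genes of glycolysis and hypoxia response 23 rose and 0 fell, and 25 and 0 adjusted over the list alone (adjusted p = 8.6e-17, and adjusted p = 0.11 with an estimated correlation). The vasodilator peptide gene adma rose by 1.51 ± 0.11. Of 38 circadian clock genes 12 rose and 0 fell, and 15 and 0 adjusted over the list alone (adjusted p = 7.6e-07, and adjusted p = 0.5 with an estimated correlation). The clock repressor gene ciarta rose by 1.02 ± 0.10, and the labels give no time of day of sampling.

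Enterocyte markers fell in OBS30 in 25 of 43 genes and rose in 0, and in 29 and 0 adjusted over the list alone (adjusted p = 8.1e-20, and adjusted p = 0.071 with an estimated correlation). The count of 25 was 15 and 16 without control replicates 2 and 3, and 14 without OBS30 replicate 3 or 4. Hepatocyte markers fell in 21 of 35 genes and rose in 3, and in 26 and 4 adjusted over the list alone (adjusted p = 4.4e-16, and adjusted p = 0.071 with an estimated correlation). The transferrin gene tfa, for iron transport, fell by 1.27 ± 0.08 while the insulin-like growth factor binding gene igfbp1a rose by 0.60 ± 0.09. Of 28 genes of lipoproteins and bile acid metabolism 15 fell and 2 rose, and 18 and 2 adjusted over the list alone (adjusted p = 4.6e-14, and adjusted p = 0.079 with an estimated correlation). The apolipoprotein genes apom and apoa2, which are in the hepatocyte list as well, fell by 1.60 ± 0.11 and 1.11 ± 0.08, and apoeb rose by 1.25 ± 0.10. Of 43 genes of complement, coagulation and acute phase 24 fell and 1 rose, and 32 and 1 adjusted over the list alone (adjusted p = 5.4e-18, and adjusted p = 0.071 with an estimated correlation). Of 21 exocrine pancreas markers 8 fell and 0 rose, and 12 and 0 adjusted over the list alone (adjusted p = 4.9e-11, and adjusted p = 0.13 with an estimated correlation). Of 51 lens genes 23 fell and 0 rose, and 29 and 0 adjusted over the list alone (adjusted p = 4.1e-18, and adjusted p = 0.071 with an estimated correlation). The lens count was 12 and 14 without control replicates 3 and 4, and 13 without OBS30 replicate 3. The crystallin gene cryaa fell by 1.08 ± 0.11. Of 57 photoreceptor genes 17 fell and 0 rose, and 22 and 0 adjusted over the list alone (adjusted p = 4.9e-11, and adjusted p = 0.13 with an estimated correlation). The photoreceptor count was 9, 8 and 6 without control replicates 2, 3 and 4, and 8, 5 and 5 without OBS30 replicates 1, 3 and 4. The cone arrestin gene arr3b fell by 1.24 ± 0.12. Neuron and glia markers had 4 higher and 4 lower of 57, and 4 and 6 adjusted over the list alone (adjusted p = 0.067). The 4 higher were 2 without any single control or OBS30 library. The 4 lower were 1 without any of those, 2 without OBS20 replicate 1 and 8 without PFOS20 replicate 4.

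In all, 2584 genes and loci were called in OBS30, 1450 higher and 1134 lower, with 587 and 414 changed by at least 2-fold. Camera called 14 lists higher and 10 lower, 0 of them with an estimated correlation. No overlap between the libraries of the groups was seen in 33.3% of all genes and loci tested, against the 10% that chance gives on average over splits. The count was 1681, 1566 and 1529 without control replicates 2, 3 and 4, and 1712, 1567 and 1488 without OBS30 replicates 1, 3 and 4. It was 3965 without OBS20 replicate 3 and 3931 after quantile normalisation.

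The compounds were compared directly at their matched dose of 20 mg/L. Part of the cytokine, wound and heat shock genes were lower in OBS20 than in PFOS20 (16 of 31, 22 of 47 and 14 of 33), and part of the neural, proliferation and pancreas genes higher (33 of 57, 27 of 50 and 13 of 21). None of these list calls held with an estimated correlation. The leptin gene lepb was 4.70 ± 0.32 lower in OBS20 on the log2 scale, where it stood at 0.717 ± 0.645 TPM against 41.3 ± 0.937 (SD, n = 3). The difference was -3.89 ± 0.39 for il1b, -3.52 ± 0.17 for pth1a, -2.84 ± 0.19 for mmp9 and -2.77 ± 0.25 for the chemokine gene cxcl18b. The neuronal tubulin gene tuba1c was higher in OBS20 by 1.48 ± 0.14, the chromatin gene hmgb2b by 0.85 ± 0.07 and the carboxypeptidase gene cpa1 of the pancreas by 1.51 ± 0.24.

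Of 31 genes of cytokines and inflammatory signalling 16 were lower in OBS20 than in PFOS20 and 0 higher, and 18 and 1 adjusted over the list alone (adjusted p = 8.3e-14, and adjusted p = 0.06 with an estimated correlation). The mean of the list differed by -0.92, with a 95% interval from -1.18 to -0.67. Of 47 genes of extracellular matrix remodelling and wound response 22 were lower and 0 higher, and 27 and 3 adjusted over the list alone (adjusted p = 2.2e-16, and adjusted p = 0.12 with an estimated correlation). Among 33 heat shock protein genes 14 were lower and 3 higher, and 15 and 3 adjusted over the list alone (adjusted p = 6.5e-08, and adjusted p = 0.12 with an estimated correlation), with 9 lower without PFOS20 replicate 3. The small heat shock gene hspb11 differed by -1.89 ± 0.14, while hspa4b was higher in OBS20 by 2.64 ± 0.42. Of 57 neuron and glia markers 33 were higher and 0 lower, and 38 and 1 adjusted over the list alone (adjusted p = 2.2e-16, and adjusted p = 0.24 with an estimated correlation). The count of 33 was 21, 20 and 19 without PFOS20 replicate 2, PFOS20 replicate 3 and OBS20 replicate 1. The mean of this list differed by 0.73, with a 95% interval from 0.33 to 1.14. That interval pools the spread of all 4 groups. The list's median against the control mean was -1.31, -1.15 and -0.62 in PFOS20, and -0.02, 0.03 and -0.02 in the control libraries. With spreads this unlike, the interval may be too narrow for this comparison. Of 50 proliferation genes 27 were higher and 0 lower, and 40 and 0 adjusted over the list alone (adjusted p = 2.0e-18, and adjusted p = 0.15 with an estimated correlation), with 16 and 17 higher without PFOS20 replicate 3 and OBS20 replicate 1. Of 21 pancreas markers 13 were higher and 0 lower, and 19 and 0 adjusted over the list alone (adjusted p = 1.3e-10, and adjusted p = 0.17 with an estimated correlation), with 6 higher without PFOS20 replicate 3.

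Further lists called lower in OBS20 than in PFOS20 included macrophage and microglia markers (adjusted p = 2.2e-08, and adjusted p = 0.06 with an estimated correlation), mitochondrially encoded genes (adjusted p = 3.3e-08, and adjusted p = 0.06), lipoproteins and bile acid metabolism (adjusted p = 5.7e-08, and adjusted p = 0.18), the unfolded protein response (adjusted p = 2.5e-07, and adjusted p = 0.24) and enterocyte markers (adjusted p = 2.9e-07, and adjusted p = 0.24). The 7 mitochondrial genes lower were 3 without PFOS20 replicate 3 or OBS20 replicate 1. The 10 lipoprotein genes lower were 5, 4 and 5 without PFOS20 replicate 2, PFOS20 replicate 3 and OBS20 replicate 1. The 11 enterocyte markers lower were 6, 3 and 3 without these in turn. The 5 unfolded protein response genes lower were 2 or 3 without any single library other than OBS20 replicate 3. Members called the other way are not counted here. The lens list was called higher (adjusted p = 4.2e-05, and adjusted p = 0.24), but not without OBS20 replicate 3 (adjusted p = 0.23). Its 14 genes higher were 6, 5 and 4 without PFOS20 replicate 2, PFOS20 replicate 3 and OBS20 replicate 1. The 4 lists that follow were among those not called. Of 31 cholesterol synthesis genes 0 were higher and 0 lower in limma, with equal counts adjusted over the list alone (adjusted p = 0.29 by camera), and the mean of the list differed by -0.04, with a 95% interval from -0.39 to 0.32. Without OBS20 replicate 3 there were 5 higher, and without PFOS20 replicate 4 or OBS20 replicate 2 there was 1 lower. For the 12 aryl hydrocarbon receptor targets 3 were higher and 1 lower in OBS20, and 4 and 1 adjusted over the list alone (adjusted p = 0.29). Their mean differed by 0.12, with an interval from -0.21 to 0.44. The count of 3 was 1 without PFOS20 replicate 2, PFOS20 replicate 3, OBS20 replicate 1 or OBS20 replicate 2, and the 1 lower was 0 without any PFOS20 replicate or OBS30 replicate 4. Photoreceptor genes had 1 higher and 2 lower of 57, equal to the counts adjusted over the list alone (adjusted p = 0.91), and a mean difference of 0.02, with an interval from -0.17 to 0.21. The photoreceptor gene counted as higher became 2 without PFOS20 replicate 2 and 3 without PFOS20 replicate 4 or OBS20 replicate 3. The 2 lower became 1 without PFOS20 replicate 2 or OBS20 replicate 1 and 0 without PFOS20 replicate 3. Antioxidant and Nrf2 targets had 8 higher and 1 lower of 49, and 9 and 2 adjusted over the list alone (adjusted p = 0.074), with 5 higher without OBS20 replicate 1. Their mean differed by 0.15, with an interval from -0.04 to 0.34. Within that list gstp1 was higher in OBS20 than in PFOS20 by 1.41 ± 0.07 (adjusted p = 7.7e-06) and prdx1 by 0.77 ± 0.11 (adjusted p = 0.0023), genes singled out in this comparison after their values were seen.

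In all, 2996 genes and loci differed between OBS20 and PFOS20, 1794 higher and 1202 lower in OBS20, with 510 and 458 by at least 2-fold. Camera called 5 lists higher and 22 lower, 0 of them with an estimated correlation. Among all genes and loci tested, 23.3% had no overlap between the libraries of the groups, against the 10% that chance gives on average over splits. The count was 1742 and 1387 without PFOS20 replicates 2 and 3, 1551 and 1945 without OBS20 replicates 1 and 2, and 6491 without OBS20 replicate 3, where 1897 differed by at least 2-fold. It was 5051 after quantile normalisation, 4570 after median-of-ratios scaling and 576 in a fit of the 6 libraries alone. The balance of directions turned with the setting. It was 226 higher and 350 lower in the fit of 6 libraries, 870 and 872 without PFOS20 replicate 2, 942 and 1003 without OBS20 replicate 2, and 5107 and 1384 without OBS20 replicate 3. At 2-fold it was 483 and 541 after quantile normalisation, 455 and 571 after median-of-ratios scaling and 152 and 262 in the fit of 6 libraries. Leaving out PFOS20 replicate 2 or 3 or OBS20 replicate 1 or 2 gave 281 and 429, 292 and 357, 314 and 425, and 329 and 485 at 2-fold, and leaving out OBS20 replicate 3 gave 1444 and 453.

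The last comparison asked what differed between the doses of OBS. Part of the wound, cytokine and circadian genes were higher in OBS30 than in OBS20 (10 of 47, 6 of 31 and 11 of 38), and part of the pancreas genes lower (6 of 21). None of these list calls held with an estimated correlation, and the circadian count was 3, 2 and 2 without OBS30 replicates 1, 3 and 4. The leptin gene lepb was higher in OBS30 than in OBS20 by 3.61 ± 0.32, mmp13a by 2.23 ± 0.22, mmp9 by 1.67 ± 0.19 and hsp70l by 1.85 ± 0.13 (n = 3 in each group). The trypsin gene prss59.1 fell by 1.76 ± 0.21 from 222 ± 66.0 to 62.9 ± 7.49 TPM (SD), the ammonium transporter gene rhcgl1 by 2.06 ± 0.22 and the hepatocyte gene tfa by 0.67 ± 0.08. Of 47 genes of extracellular matrix remodelling and wound response 10 were higher and 0 lower, and 22 and 0 adjusted over the list alone (adjusted p = 9.8e-13, and adjusted p = 0.2 with an estimated correlation), with 6 higher without OBS30 replicate 3. Of 31 cytokine and inflammatory genes 6 were higher and 0 lower, and 16 and 0 adjusted over the list alone (adjusted p = 9.2e-11, and adjusted p = 0.091 with an estimated correlation), with 3 higher without OBS30 replicate 3. The signalling inhibitor gene socs3a was higher by 1.53 ± 0.15. Of 21 pancreas markers 6 were lower and 0 higher, and 12 and 0 adjusted over the list alone (adjusted p = 1.6e-22, and adjusted p = 0.1 with an estimated correlation).

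Of 38 circadian clock genes 11 were higher in OBS30 than in OBS20 and 0 lower, and 18 and 0 adjusted over the list alone (adjusted p = 6.1e-13, and adjusted p = 0.32 with an estimated correlation). The count of 11 was 7, 6 and 7 without control replicates 2, 3 and 4, 7 without PFOS20 replicate 3, 3 without OBS30 replicate 1 and 2 without OBS30 replicate 3 or 4. The list's median against control was -0.61 in OBS20 replicate 3, against 0.09 and 0.10 in OBS20 replicates 1 and 2 and 0.28, 0.35 and 0.45 in OBS30. Without OBS20 replicate 3 the count was 8 (adjusted p = 3.4e-12). The clock-linked repressor gene nfil3 was higher by 0.98 ± 0.11. Ribosomal protein transcripts took 14.4% ± 0.736 of TPM in OBS30 against 16.8% ± 2.05 in OBS20 (SD, n = 3), and OBS20 replicate 3 was the highest of all libraries at 19.1%.

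In all, 484 genes and loci differed between the doses, 341 higher and 143 lower in OBS30. Among all genes and loci tested, 16.8% had no overlap between the libraries of the groups, against the 10% that chance gives on average over splits, and this gap was not tested. Of those called 153 and 41 differed by at least 2-fold, against 119 and 67 after quantile normalisation, and the 2-fold total of 194 was 87 and 117 without OBS30 replicates 3 and 4. Camera called 10 lists higher and 11 lower, 0 of them with an estimated correlation. The median of all genes was 0.10 as scaled by the authors and -0.02 after quantile normalisation. The share called higher was 70.5%, against 56.0% after quantile normalisation. The count was 266 without OBS20 replicate 1, 240, 140 and 184 without OBS30 replicates 1, 3 and 4, 803 after quantile normalisation and 88 in a fit of the 6 libraries alone.

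The overlap of the responses to the exposures was counted across genes. PFOS20 and OBS20 shared 152 genes called higher and 148 called lower, where independent calls would give 13.3 and 29.5, and 10 were called in opposite directions. PFOS20 and OBS30 shared 891 higher and 613 lower, where independent calls would give 92.0 and 135, with 21 in opposite directions. OBS20 and OBS30 shared 187 higher and 226 lower, where independent calls would give 9.88 and 9.13, with 0 in opposite directions. Across 30674 genes the log2 changes had a Pearson r of 0.51, 0.61 and 0.62 and a Spearman rho of 0.53, 0.59 and 0.58 for these pairs in turn. Genes are not independent replicates, and the comparisons share their 3 control libraries, so independent calls are not the level to expect without a change. Simulated groups without a change shared simulated controls, all drawn around the control means with residuals shuffled over the 12 libraries. They gave r from -0.63 to 0.87, from -0.19 to 0.79 and from -0.07 to 0.85, ranges that hold the observed values. The simulated controls carried the spread of all groups, OBS20 replicate 3 included. The real controls may give other ranges of r and of covariance. In the 20 draws that were also tested, shared calls in the same direction numbered at most 0 for each pair. The draws held no change, so hardly any gene could be called in them and this result was nearly fixed. It cannot give the overlap to expect of real but unrelated responses. The covariance was 0.135, 0.200 and 0.142, where the highest simulated values were 0.155, 0.165 and 0.195, so that of PFOS20 and OBS30 lay above its simulated range. All pairs were simulated alike, so their highest values differ only by the draw. The 0.200 of PFOS20 and OBS30 was close to the highest over all pairs, 0.195. An F test over the 3 exposures called 5009 genes and loci, which became 3287 and 2815 without PFOS20 replicates 2 and 3, 9114 without OBS20 replicate 3 and 7815 after quantile normalisation.

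**Figure D3:**
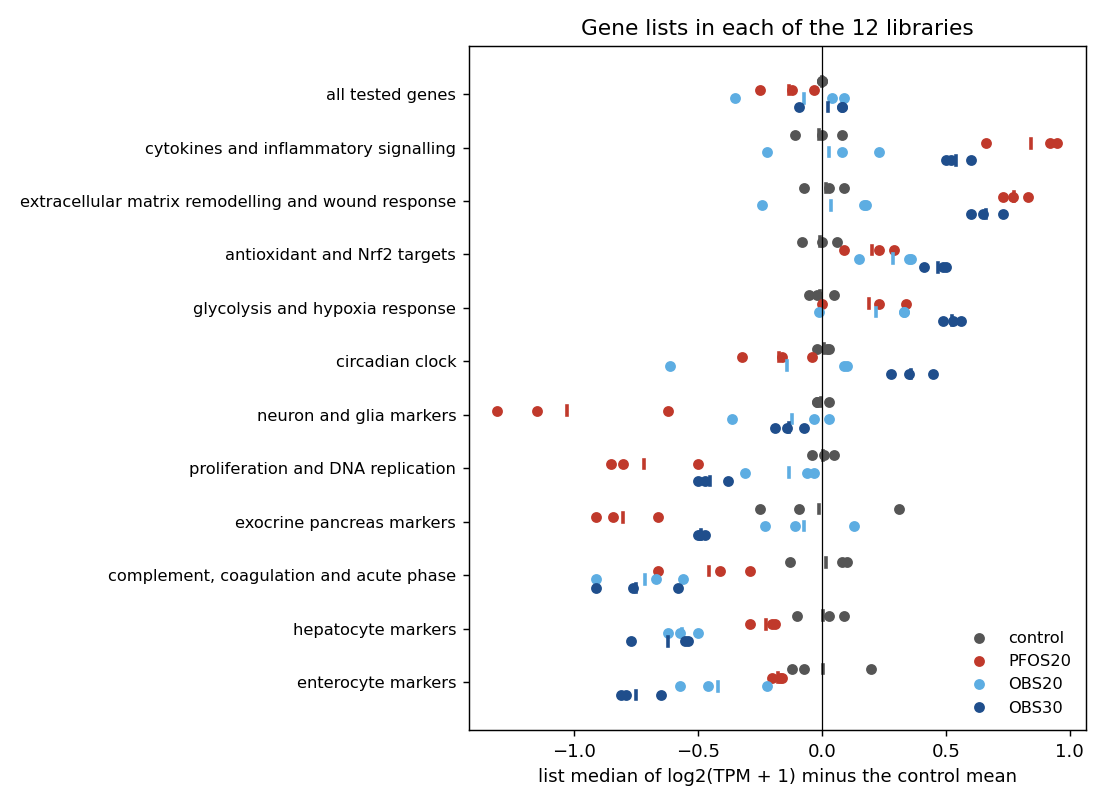
Median over the genes of a list of log2(TPM + 1) minus the control mean, for 11 gene lists and for all tested genes, with 1 point per library and a tick at the group mean. The neuron and glia markers of PFOS20 lie at -1.31, -1.15 and -0.62, and those of OBS20 replicate 3 at -0.36, where all its genes have a median of -0.35.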

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

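The tests of hepatocyte number and developmental delay, and the split by direction in the test of a mislabelled PFOS20 library, were chosen after the result was seen.

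At 20 mg/L 10 genes were called against control in opposite directions for the compounds. The direct test also called all 10, which adds no further support. In the same fit the direct difference is that between the opposite changes, so the selection nearly fixed this call. Of the 10 genes 7 were higher in PFOS20 and lower in OBS20, and 3 the reverse. The uncoupling protein gene ucp1 changed by 0.61 ± 0.15 in PFOS20 and by -1.14 ± 0.15 in OBS20 (n = 3 in each group). The gene plekhs1 changed by 0.94 ± 0.17 and -2.37 ± 0.17. The 3 lower in PFOS20 and higher in OBS20 were the haem synthesis gene alas1, at -0.52 ± 0.12 and 0.62 ± 0.12, ptgdsb.2, at -0.32 ± 0.09 and 0.43 ± 0.09, and zgc:193505, at -0.48 ± 0.13 and 0.94 ± 0.13. Of these plekhs1 was named by the rule, and the others were chosen after their values were seen. The median difference between OBS20 and PFOS20 was 0.88 over the neuron and glia markers and -0.79 over the cytokine and inflammatory list (0.84 and -0.83 relative to all genes). Camera called these differences at its preset correlation (adjusted p = 2.2e-16 and 8.3e-14) and did not with an estimated correlation (adjusted p = 0.24 and 0.06).

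The first pattern weighed was the lower level of neuron and glia markers in PFOS20, with a median of -1.03 (-0.90 relative to all genes) and 35 of 57 called lower, and with adjusted p = 0.29 for the list with an estimated correlation. With each library's trend over gene length removed, 35 of those stayed called lower, and with median-of-ratios scaling 34 did, which argues against a length trend or library scaling as the whole cause. Without PFOS20 replicate 2 the median was -0.92 and 29 were called lower, which argues against that library alone. Fewer or less mature neural cells after PFOS, or lower transcription in them, may account for it, and bulk RNA does not separate these.

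The second pattern was the lower level of hepatocyte markers in OBS30, with a median of -0.62 (-0.64 relative to all genes) and 21 of 35 called lower, and with adjusted p = 0.071 for the list with an estimated correlation. The markers did not change alike: 62.86% of them, 22 genes, had a 95% interval that left out the median, and 4 lay above 0. This cannot decide on a lower number of hepatocytes. The log2(TPM + 1) scale shrinks the changes of genes with low TPM, and members can respond in other ways. One of them, igfbp1a, is also in the glycolysis and hypoxia list. Median-of-ratios scaling kept 17 of the 21. Younger larvae divide more, whereas the proliferation list had a relative median of -0.48 (camera, adjusted p = 5.9e-17, and adjusted p = 0.13 with an estimated correlation). Of its 50 genes 16 were called lower, and 7, 6 and 6 without control replicates 2, 3 and 4. That count was 7, 8 and 6 without OBS30 replicates 1, 3 and 4, and 25 without OBS20 replicate 3. This cannot decide on developmental delay, because a delay together with slower division would also lower these genes. No larvae of other ages were sequenced. Fewer hepatocytes, a developmental delay or a changed output of hepatocytes after OBS may account for the pattern, and these were not told apart.

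The third pattern was OBS20 replicate 3, which stood apart from the other OBS20 libraries. Without the 100 most abundant genes its median TPM was 0.631 of their mean, against 0.579 with all genes, which argues against a few abundant genes as the cause. On a scale from those libraries (0) to OBS30 (1), it lay at a median of 0.05 over 141 genes, which argues against a mislabelled OBS30 library. On the scale to PFOS20 it lay at 0.52 over 1897 genes, between the bounds that were set for the scale to OBS30. Split by direction, it lay at 0.00 for 453 genes higher in PFOS20 (quartiles -0.18 and 0.27) and at 0.68 for 1444 lower, which argues against a mislabelled PFOS20 library. Lower RNA quality or library complexity may account for it, and stays open because the labels give a minimum RNA quality but no value per library.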

How the results depend on the processing

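The length-trend alternatives and the list tests without OBS20 replicate 3 were chosen after the data were seen, and the length trend was first removed together with each library's level and then with that level kept. No called change of a named gene changed sign under the alternatives run, and no list passed in the other direction, but the balance of genes higher and lower did turn. For OBS20 against PFOS20 it went from 1794 and 1202 to 226 and 350 with only the 6 libraries, 870 and 872 without PFOS20 replicate 2 and 942 and 1003 without OBS20 replicate 2. For OBS20 against control it went from 209 and 247 to 348 and 255 with quantile normalisation, 241 and 212 with median-of-ratios scaling, 239 and 194 at a mean TPM of at least 5, 212 and 209 with the smaller pseudocount, 55 and 54 with only the 6 libraries, 124 and 123 without control replicate 2, 302 and 203 without OBS20 replicate 3 and 339 and 262 with trend and level removed. For PFOS20 against control it went from 1947 and 3663 to 3590 and 3577 with median-of-ratios scaling and 3921 and 3707 with trend and level removed. Quantile normalisation moved the counts of OBS30 against control to 3931, OBS20 against PFOS20 to 5051, OBS30 against OBS20 to 803 and the F test to 7815, and median-of-ratios scaling moved OBS20 against PFOS20 to 4570. With trend and level removed, OBS20 against PFOS20 gave 5073 and the F test 7577. These settings even out the level of the libraries, and the cause was not tested further. Only the 6 libraries gave 109 for OBS20 against control, 576 for OBS20 against PFOS20 and 88 for OBS30 against OBS20. Such fits gave 6667 and 3491 for PFOS20 and OBS30 against control, where OBS20 replicate 3 does not enter the residual. Leaving out that library alone raised these counts as well, to 8716 and 3965. The cause was not tested further. A block for the replicate number gave 3634, 136, 1150, 1389 and 133 for PFOS20, OBS20 and OBS30 against control, OBS20 against PFOS20 and OBS30 against OBS20, and 2311 for the F test. Replicates with the same number did not deviate together (r from -0.11 to 0.10 over 13 pairs, and from -0.19 to 0.25 over 41 others), and not every library correlated best with its own number. Leaving out 1 library gave, in the same order, 3090 to 8716, 230 to 505, 1488 to 3965, 1387 to 6491, 140 to 427 and, for the F test, 2815 to 9114. The lowest were without PFOS20 replicate 3, OBS20 replicate 1, OBS30 replicate 4, PFOS20 replicate 3, OBS30 replicate 3 and PFOS20 replicate 3. The highest were without OBS20 replicate 3, except 427 without PFOS20 replicate 2. Counts at 2-fold moved to 1485 for OBS20 against PFOS20 with a pseudocount of 0.1, and to 1245 and 654 for PFOS20 and OBS30 against control at a mean TPM of at least 5, where fewer genes were tested. They also moved with the block, to 117 for OBS20 against control and 93 for OBS30 against OBS20, and with only the 6 libraries, to 87 and 67 for these and 414 for OBS20 against PFOS20. Under other pseudocounts, filters and scalings the r between responses stayed from 0.49 to 0.52, 0.59 to 0.61 and 0.58 to 0.62. Of 118 list calls by camera, 2 held with an estimated correlation, 109 with the replicate block, 108 with median-of-ratios scaling and 112 with quantile normalisation. With the smaller pseudocount 118 held, and without OBS20 replicate 3 107 did. Fry, which tests a list for a change of its own rather than against other genes, called 89 of them in the same direction. Of 361 results for named genes, 63 lost a call with the block, 46 with median-of-ratios scaling, 9 with quantile normalisation and 66 in fits of the 6 libraries alone. Counted over all fits that left out 1 library, results for named genes lost a call 319 times, gained one 3 times and stayed the same 4010 times. TPM without counts leaves the depth limit unknown.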

Other observations

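The tests of pathway maps were chosen after the data were seen, and the maps given here were picked after their values were seen. The annotation in the table assigns genes to KEGG maps, of which 306 with 15 to 400 genes were tested by camera, and 0 of the calls in any contrast held with an estimated correlation. Maps passed as higher and lower numbered 54 and 30 in PFOS20, 18 and 10 in OBS20, 53 and 29 in OBS30, 31 and 67 in OBS20 against PFOS20, and 86 and 33 in OBS30 against OBS20. Medians of maps are unadjusted. Among 175 spliceosome genes 52 fell and 7 rose in PFOS20, with a median of -0.35 (adjusted p = 3.3e-06, and adjusted p = 1 with an estimated correlation), and 32 were higher and 6 lower in OBS20 than in PFOS20. Of 119 genes of the synaptic vesicle cycle 44 fell and 7 rose in PFOS20 (adjusted p = 3.3e-04, and adjusted p = 1 with an estimated correlation). The map of xenobiotic metabolism by cytochrome P450 had 15 of 66 genes higher and 3 lower in OBS20 (adjusted p = 1.9e-10, and adjusted p = 0.81 with an estimated correlation), and 15 higher and 0 lower in OBS20 than in PFOS20 (adjusted p = 9.2e-04, and adjusted p = 1 with an estimated correlation). Of 36 genes of vitamin digestion and absorption 11 fell and 1 rose in OBS30 (adjusted p = 1.1e-04, and adjusted p = 1 with an estimated correlation). Among 165 ribosome genes 21 fell and 0 rose in OBS30, with a median of -0.22 (adjusted p = 1.2e-11, and adjusted p = 1 with an estimated correlation).

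The 10 splits of 3 against 3 libraries are too few for a share under 0.05. In 1 of 10 splits, the real one, PFOS20 against control gave 5610 genes, where the highest other gave 3. For OBS20 against control 1 of 10 gave 456, and the highest other 1. For OBS30 against control 1 of 10 gave 2584, and the highest other 2. For OBS30 against OBS20 1 of 10 gave 484, and the highest other 3. For OBS20 against PFOS20, 2 of 10 splits gave as many genes as the real 2996. The other split, PFOS20 replicates 2 and 3 with OBS20 replicate 3 against the rest, gave 3263 and points to a structure of the samples. These are the libraries with the lowest median TPM, at 1.57, 1.80 and 1.27. For the F test, 1 of 100 regroupings of the 12 libraries, the real one, gave 5009 and the highest other 2692. This is the lowest share that 100 regroupings can give, so chance was unlikely for that count but not excluded.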
